A study of Mus musculus with 6 samples.

How the data were processed

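RNA from the quadriceps of 6 C57BL/6 mice at 0 days of age was measured on Illumina bead arrays, 1 array per mouse, with 3 Klhl40 knockout (KO) and 3 wild-type (WT) animals grouped by the genotype in the labels. Per the labels' protocols, RNA was extracted with Trizol and Cy3-labelled cRNA was made with an Ambion MessageAmp kit. The scanner and its software are not given in the sources used here. The authors deposited a table that, per the file headers, gives for each probe and array the mean bead intensity, the standard error of the bead intensity, the count of beads and a detection p-value. The values show an intensity on a linear scale without background subtraction, with medians of 111 to 113 per array. The detection p-value moved in steps of 1 in 936, the number of control values it was read against. The authors also deposited a second table of 1 intensity per probe and array, with a median of 112 in each of the 6 columns. Its scale was read from the values: it is linear, its sorted columns differed by at most 0.466, as quantile normalisation gives, and each column correlated best with its own array (r of 1.00 on the log2 scale across probes).

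Of 45281 probes, 34885 carried 1 gene symbol, 18 carried several and 10378 carried none in the table that pairs probes with genes. Of the 34885, 34807 had a symbol found in the RefSeq gene table of assembly GRCm38.p6, which was used for names and for the order of neighbouring genes alone, and no symbol was changed. The bead intensities were normalised with the neqc function of limma 3.58.1 in R 4.3.3. This step removes background by the normexp model with the negative controls inferred from the detection p-values, adds an offset of 16, applies quantile normalisation and takes log2. A probe was kept when its detection p was under 0.05 on at least 3 of the 6 arrays, which left 19099 probes. The probe with the highest mean over all 6 arrays stood for its gene, and 3894 genes had more than 1 detected probe. This gave 13455 genes, of which 10493 had a symbol and 2962 were probes without one, tested as themselves.

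KO was compared with WT by limma (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over the 13455 genes and a threshold of 0.05. Gene lists were tested against all other genes by limma's camera with a preset correlation of 0.01, with camera again at an estimated correlation and with limma's fry, which tests whether the genes of a list move on balance in one direction. The lists were adjusted as 1 family, and a list needed 5 measured members. The design, the lists, the rule for named genes and the alternatives were fixed before the data were examined. The 25 lists covered muscle processes (thin filament and nemaline myopathy; thick filament, titin and M-band; Z-disc and intermediate filament; slow, fast, and embryonic and neonatal fibres; myogenic regulators; neuromuscular junction and denervation; excitation-contraction coupling), state (atrophy, fasting, oxidative phosphorylation, glycolysis, chaperones, endoplasmic reticulum stress, cell cycle) and other cells (fibroblast, macrophage, endothelial, erythroid, adipocyte, Schwann, smooth muscle, cartilage and bone, keratinocyte), and 24 could be tested. Named were Klhl40, then up to 10 genes with the largest rise and 10 with the largest fall among those past the threshold whose KO and WT values do not overlap. For each process list up to 4 members past the threshold followed, or the 2 with the smallest p where none passed, and for each cell type list the 2 with the smallest p. Neb, Lmod3, Klhl41 and Acta1 were named whatever their p, and probes without a gene name were counted and not named. Other list members are examples chosen after their values were seen.

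The design text states that each KO mouse was killed with a WT littermate, and the replicate numbers come from the sample titles. Deviations from the group means correlated by 0.33, 0.22 and 0.46 between arrays with the same number (0.32, 0.16 and 0.46 without sex-linked genes). Between arrays with different numbers they correlated by -0.41 to 0.24 (-0.43 to 0.29 without sex-linked genes). WT 2 correlated more with KO 1 (0.24, and 0.29 without sex-linked genes) than with KO 2 (0.22 and 0.16), so the second pair is not borne out from the side of WT 2. From the side of KO 2, WT 2 was the closest WT array. KO 2 correlated by 0.003 with WT 1 and -0.17 with WT 3 (0.05 and -0.15 without sex-linked genes). The numbers were nevertheless taken to pair the littermates, as an assumption. The female-specific transcript Xist gave 11.18 on WT 2 and 11.21 on KO 2, against 4.28 to 5.66 on the other 4 arrays, and the Y-linked gene Eif2s3y gave 4.34 and 4.31 against 7.46 to 7.91, so the arrays of each pair were alike in these genes. The Xist probe was detected on 4 arrays. It gave 4.965 on WT 3 and 5.662 on KO 3, both with the Y-linked signal, against 4.278 on WT 1 and 4.332 on KO 1. The source of this low signal was not tested. The main comparison was unpaired, and it was repeated with the replicate numbers as a block, called the littermate block or pairs below.

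Each array detected 18373 to 19189 probes (40.6% to 42.4%), with a median of 42 to 43 beads per probe and a median bead standard error of 3.02% to 3.16% of the signal of detected probes. Arrays of the same group differed beyond the bead noise at 22.7% to 42.4% of the probes, so no array was a copy of another. The number of arrays limits the precision. The steps were tested on simulated data for the KO against WT comparison with 13455 genes. Of 100 genes changed by 1 on the log2 scale 80% were recovered, of 100 changed by 2 97%, and 8 of 185 calls were false. With the block 58% and 90% were recovered. No pair effect was simulated, so this cannot show whether the block gains or loses power in the data. In the data 1473 genes had an unadjusted limma p under 0.05 with the block, against 978 without it. A planted list of 20 genes shifted by 0.5 was called by camera (adjusted p = 1.29e-22), and 0 of 100 unchanged lists were called. The simulated genes varied independently of each other. In the data the estimated correlation was 0.38 in the Z-disc list, 0.60 in the slow fibre list and 0.86 in the adipocyte list. The simulation therefore does not test how often camera falsely calls a list of correlated genes.

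Each result was also computed with no background correction, normexp with an offset of 50 and no controls, median centring in place of quantile normalisation, the authors' second table, no detection filter, and a detection p under 0.01 on all 6 arrays. The littermate block and leaving out each array in turn were also run for each result. The counts of genes alone were computed with eBayes with trend and robust settings, array weights, a log2 difference of at least 1 and an adjusted p under 0.1. Every probe tested as itself was run for the counts and Klhl40, and the other list tests for the lists. A range over alternatives covers the settings run for that result. A slide block was not run, because the headers name no slide. Testing the lists without their called members was added after the data were seen.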

Results

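Gene expression was measured in the quadriceps, a thigh muscle, of C57BL/6 mice at 0 days of age with Illumina bead arrays. Tissue from 3 mice lacking Klhl40 (KO) was compared with tissue from 3 wild-type mice (WT), 1 array per mouse. Klhl40 encodes a muscle-specific kelch protein that binds nebulin and leiomodin-3, and loss of the human gene causes nemaline myopathy, a muscle weakness with thin-filament rods. The design asked which muscle genes differ between the genotypes at birth, before poor feeding could alter them. Each array detected between 18373 and 19189 of 45281 probes, and 13455 genes were tested. Levels are given as log2 normalised intensity, and differences as KO minus WT.

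Klhl40 was measured first, because its level checks the genotype labels. It fell from 10.72 ± 0.08 (SD, n = 3) in WT to 4.99 ± 0.66 (SD, n = 3) in KO, a difference of -5.73 (SE 0.29, limma adjusted p = 0.00115). On the scanner's own scale its mean intensity was 1786 ± 129 in WT and 122 ± 15.7 in KO (SD, n = 3 each). The probe was detected on all 3 WT arrays and on 1 of the 3 KO arrays, KO 2, with a detection p of 0.00107. The KO level therefore lay near the background, and the size of the difference depended on the background correction, at -3.87 without it. The array carried 1 detected probe for Klhl40, and whether it lies inside the deleted part of the gene is not given in the sources used here. The call was kept without each array in turn.

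Ankrd2, a titin-binding ankyrin repeat protein of slow fibres, rose from 8.98 ± 0.42 to 12.01 ± 0.17 (SD, n = 3 each), an 8.16-fold change. Its relative Ankrd1, which also binds titin, rose by 1.80 (SE 0.15, limma adjusted p = 0.0112), and a second Ankrd1 probe gave 1.95. Csrp3, the muscle LIM protein of the Z-disc, rose from 12.23 ± 0.39 to 13.80 ± 0.05, and Xirp2, an actin-binding repeat protein, rose by 1.24 (SE 0.14). Hspb7, a small heat shock protein of striated muscle, rose from 9.37 ± 0.07 to 10.87 ± 0.18, a 2.82-fold change. Mettl21c, a lysine methyltransferase of skeletal muscle, rose by 1.85 (SE 0.22), and Myh1, the fast IIx myosin heavy chain, rose by 1.49 (SE 0.15). Tnfrsf12a, the receptor for the cytokine TWEAK, rose by 1.40 (SE 0.14), and Otulin, a deubiquitinase for linear ubiquitin chains, rose by 1.10 (SE 0.11). The carboxylesterase gene Ces5a rose by 1.54 (SE 0.15) from a level detected on 1 of the 3 WT arrays, and by 0.55 without background correction. The limma adjusted p of these genes lay between 0.00536 for Ankrd2 and 0.0357 for Mettl21c and Csrp3. With the littermate pairs as a block in limma, Xirp2 lost its call with an adjusted p of 0.0603, within a range of 0.0140 to 0.169 over its alternatives. The second Myh1 probe, close to background at a mean log2 of 4.89, gave 0.65 with a limma adjusted p of 0.357.

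Fewer genes fell. Myl9, a regulatory light chain of smooth muscle and non-muscle myosin, fell from 10.98 ± 0.29 in WT to 9.56 ± 0.14 in KO (SD, n = 3 each), a difference of -1.42 (SE 0.16, limma adjusted p = 0.0318). Aqp4, the water channel of the fast fibre membrane, had a difference of -1.14 (SE 0.15, limma adjusted p = 0.0472), which was -0.72 without background correction. Hhatl, a relative of the hedgehog acyltransferase and the gene annotated next to Klhl40 in the assembly GRCm38.p6, had a difference of -0.98 (SE 0.11, limma adjusted p = 0.0318). Fam78a had a difference of -0.84 (SE 0.10, limma adjusted p = 0.0409), and lost its call with the littermate block at an adjusted p of 0.0537, within a range of 0.0140 to 0.212 over its alternatives.

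**Figure D1:**
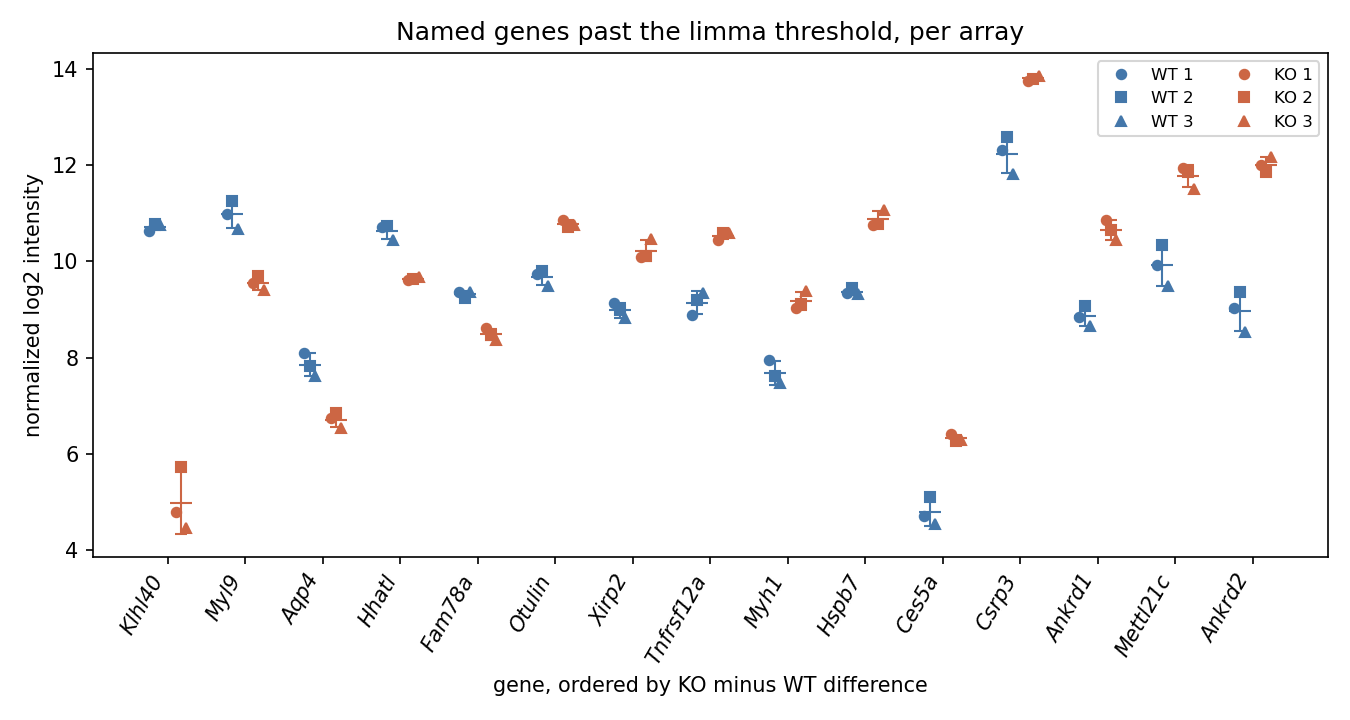
Log2 normalised intensity of the 15 genes named by the rule and past the limma threshold on each of the 3 WT and 3 KO arrays, with a point per array and bars for the mean and SD. The KO points lie on one side of all WT points for each gene, with Ankrd2 at 8.98 in WT and 12.01 in KO.

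In all, 15 genes were higher and 5 lower in KO at a limma adjusted p under 0.05, and 978 genes had an unadjusted p under 0.05. Of the 15, 11 had a gene name and 4 were probes without one. The eleventh named gene, Fcer1a, the alpha chain of the mast cell IgE receptor, rose by 0.86 (SE 0.10, limma adjusted p = 0.0341, and 0.0504 with the littermate block) and was named after its values were seen. Its WT mean of 5.55 lay near background. For all 20 genes the KO and WT values did not overlap, which held for 1796 of the 13455 genes (13.3%, where chance gives 10%). With the littermate block limma called 18 genes higher and 8 lower, of which 12 and 4 were among the 15 and 5. Without WT 1 limma called 0 genes higher and 1 lower (772 at an unadjusted p under 0.05), without KO 1 it called 0 and 1 (640), and without KO 2 it called 1 and 1. Without WT 2 it called 6 higher and 1 lower, without KO 3 it called 3 and 1, and without WT 3 it called 15 and 10. Of the 15 genes described above besides Fcer1a, 14 kept their call without WT 3, 7 without WT 2, 4 without KO 3, 2 without KO 2 and 1, Klhl40, without WT 1 or KO 1. None of the 15 changed direction, and without each array in turn the difference stayed between 2.83 and 3.22 for Ankrd2 and between 1.40 and 1.55 for Hspb7.

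Genes of the Z-disc and of slow fibres were higher together. All 12 measured slow fibre genes had a positive difference (median 0.53, mean 0.76), and 2 of them, Ankrd2 and Csrp3, rose over all genes tested, against 9 adjusted over the list alone. Among the others, Myl2, the slow myosin regulatory light chain, had a difference of 0.84, Myh7, the slow myosin heavy chain, 0.70, Tnni1, the slow troponin I, 0.63, and Tpm3, the slow tropomyosin, 0.52. Of 20 measured Z-disc and intermediate filament genes, 17 had a positive difference (median 0.44, mean 0.55), and 3 of them, Ankrd2, Xirp2 and Csrp3, rose over all genes, against 11 adjusted over the list alone. Differences that did not pass over all genes were 0.81 for Nrap, 0.71 for Myot, 0.58 for Tcap and 0.25 for Des. Against all other genes, camera gave both lists an adjusted p of 2.68e-14. With an estimated correlation the camera adjusted p was 0.308 for both, and fry gave 0.0468 for the Z-disc list and 0.0683 for the slow fibre list. Over all alternatives the adjusted p lay between 9.05e-17 and 0.308 for the Z-disc list and between 1.31e-16 and 0.308 for the slow fibre list, and both kept their camera call without each array in turn. The lists share Ankrd2, Csrp3 and Myoz2. Without their called members both kept a camera call, at a mean of 0.30 (adjusted p = 1.63e-08) for the Z-disc list and 0.45 (adjusted p = 9.54e-09) for the slow fibre list, a check chosen after the values were seen. This check and the fits without each array used the preset correlation of 0.01. The estimated correlation was 0.38 in the Z-disc list and 0.60 in the slow fibre list, and neither check was run with it.

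**Figure D2:**
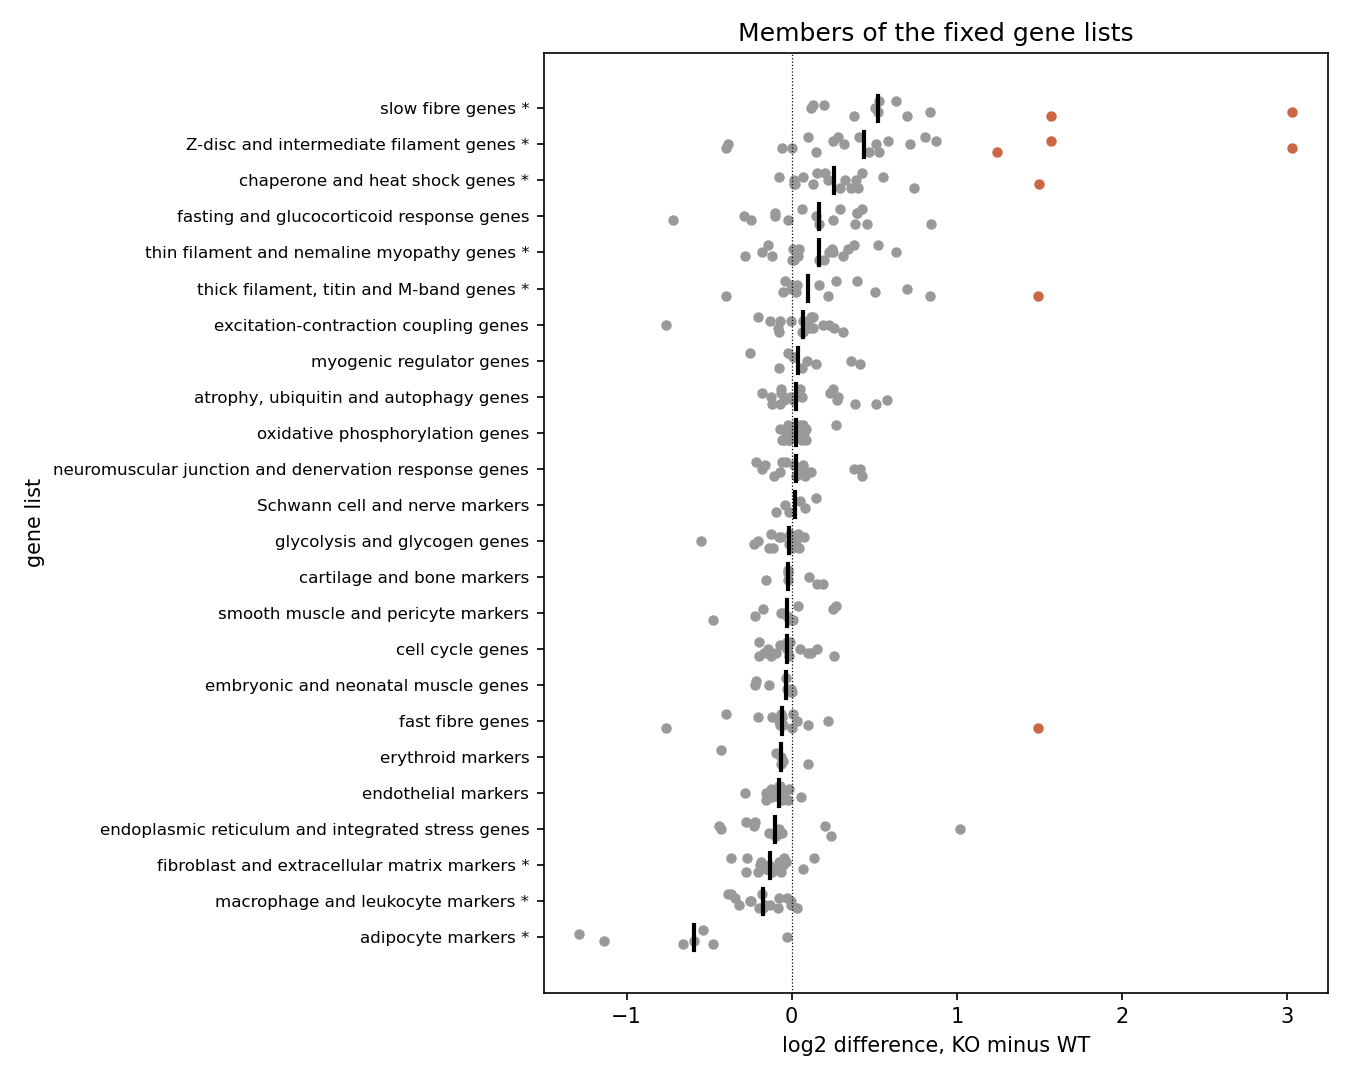
Log2 difference (KO minus WT, horizontal axis) of every measured member of the 24 tested gene lists, with a point per gene, red where it passed the limma threshold over all genes, a bar at the list median and an asterisk for lists called by camera at the preset correlation. The slow fibre list (median 0.53) and the Z-disc list (median 0.44) lie highest, and the adipocyte list (median -0.59) lies lowest.

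Chaperone genes were also higher in KO as a group. Of 18 measured members 17 had a positive difference (median 0.26, mean 0.32), and 1, Hspb7, rose over all genes, against 4 adjusted over the list alone. The alpha B-crystallin gene Cryab had a difference of 0.56, the co-chaperone gene Bag3 0.40 and Hspb1 0.39. The inducible Hsp70 gene Hspa1a had 0.74 from a level near background, detected on 1 of the 3 WT arrays. The camera adjusted p of the list was 1.93e-08, with 0.226 for the camera adjusted p with an estimated correlation and 0.0468 by fry. Without Hspb7 the list kept its camera call at the preset correlation (mean 0.25, adjusted p = 1.70e-06), and over all alternatives its adjusted p lay between 1.19e-09 and 0.226.

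Thin and thick filament genes shifted less. Both lists share members with the slow fibre list: Tnnt1, Tnni1, Tnnc1 and Tpm3 in the thin filament list, and Myh7, Myl2 and Myl3 in the thick filament list. Neither list was tested without these members. The genes tied most closely to Klhl40 did not pass the test: leiomodin-3 (Lmod3) had a difference of 0.23 (SE 0.11), the kelch paralogue Klhl41 0.16 (SE 0.09) and skeletal actin (Acta1) 0.04 (SE 0.09). Nebulin (Neb) had 0.01 (SE 0.22) from a probe near background at 5.73 ± 0.20 in WT, and -0.03 with median centring. None of the 19 thin filament and nemaline myopathy genes passed over all genes, and 1, Tnni1, passed adjusted over the list alone. That list had a median of 0.16 and a mean of 0.14 (camera adjusted p = 0.00461, and adjusted p = 0.476 with an estimated correlation), and without KO 3 its mean was 0.10 with an adjusted p of 0.140, within a range of 0.000259 to 0.476 over its alternatives. Among 16 thick filament, titin and M-band genes, Myh1 rose over all genes, and adjusted over the list alone 2 rose, Myh1 and Myl2, and 1 fell, Mybpc2, the fast myosin binding protein, at -0.40. Their median was 0.10 and their mean 0.26 (camera adjusted p = 0.00176, and adjusted p = 0.481 with an estimated correlation). Without WT 3 the mean was 0.19 with a camera adjusted p of 0.0634, within a range of 0.000260 to 0.481 over its alternatives. Myh8, the neonatal myosin heavy chain, was the brightest probe on all 6 arrays, so that the normalisation sets its difference to 0, and its scanner intensity was 39299 ± 1046 in WT and 37936 ± 174 in KO (SD, n = 3 each). Acta1, Tnnc2, Mylpf and Myl1 were also bright, at ranks 8 to 30 from the brightest. There the normalisation can hold a difference near 0, and how far this lowered the shift of both lists was not tested. On the scanner's scale Acta1 had 29238 ± 1207 in WT and 29640 ± 994 in KO. Myl1 had 33008 ± 374 in WT and 30785 ± 205 in KO (SD, n = 3 each).

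Fast fibre genes did not pass as a group. Of 15 measured, Myh1 rose over all genes, and adjusted over the list alone Myh1 rose and 2 fell, Pvalb, the calcium buffer parvalbumin, at -0.76 and Mybpc2. The list's median was -0.06 and its mean 0.0028, and the camera test pointed down (adjusted p = 0.487). Embryonic and neonatal muscle genes, 8 measured with Myh8 fixed at 0 and the others negative, had a median of -0.03 (camera adjusted p = 0.187), with -0.22 for the cardiac actin Actc1 and -0.22 for the fetal acetylcholine receptor subunit Chrng. Myogenic regulator genes had a median of 0.04 over 10 (camera adjusted p = 0.212), with 1, Myog at 0.41, past the threshold adjusted over the list alone, and Myf6 at 0.36. Neuromuscular junction and denervation genes had a median of 0.02 over 17 (camera adjusted p = 0.427), with 2, Myog and the junction adaptor Dok7 at 0.38, past the threshold adjusted over the list alone. Dok7 lay near background, at 5.26 in WT. Excitation-contraction coupling genes had a median of 0.07 over 19 (camera adjusted p = 0.414), with Pvalb, also a member here, at -0.76 and Jph1, a junctophilin of the triad, at 0.31. That last list passed without WT 2 (mean 0.09, camera adjusted p = 0.0385, within a range of 0.0385 to 0.823 over its alternatives) and had a mean of -0.04 without WT 3.

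Lists on wasting, feeding and energy supply did not pass. The tests compare the genotypes, so a state shared by arrays of both would not appear in them. Atrophy, ubiquitin and autophagy genes had a median of 0.03 over 18 (camera adjusted p = 0.0886), with the muscle ubiquitin ligase Trim63 at 0.58, and Psmd11, a proteasome subunit at 0.51, the 1 member past the threshold adjusted over the list alone. Fasting and glucocorticoid response genes had a median of 0.17 over 17 (camera adjusted p = 0.152), with the glucocorticoid-induced Tsc22d3 at 0.43 and Txnip at -0.24. Oxidative phosphorylation genes had a median of 0.03 over 26 (camera adjusted p = 0.469), with Ndufb5 at 0.27 and Cox7a1 at 0.09. Glycolysis and glycogen genes had a median of -0.02 over 17 (camera adjusted p = 0.0968), with the phosphorylase kinase subunit Phkg1 at -0.55 and Pgm1 at -0.23. Endoplasmic reticulum and integrated stress genes had a median of -0.10 over 14 (camera adjusted p = 0.212), with Nupr1 at -0.44 and the stress transcription factor Atf3 at 1.02, the 1 member past the threshold adjusted over the list alone. Atf3 lay near background, at 5.63 in WT. Cell cycle genes had a median of -0.03 over 18 (camera adjusted p = 0.508), with Top2a at 0.25 and Ccne1 at -0.17. Leaving out 1 array moved 4 of these lists past the camera threshold. Atrophy genes passed without WT 2 (mean 0.13, adjusted p = 0.0419, within a range of 0.0419 to 0.430 over the alternatives) and fasting genes without KO 1 (mean 0.22, adjusted p = 0.0325, range 0.0325 to 0.630). Glycolysis and cell cycle genes passed without WT 3 (means -0.13 and -0.13, adjusted p = 0.0146 for both), within ranges of 0.0146 to 0.660 and 0.0146 to 0.975.

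Among lists of cells other than muscle fibres, camera at the preset correlation called 3 lower in KO, those of fibroblasts, macrophages and adipocytes. Of 20 fibroblast and extracellular matrix markers 18 had a negative difference (median -0.13, camera adjusted p = 0.00298, and adjusted p = 0.349 with an estimated correlation), with the proteoglycan Lum at -0.36 and Timp1, an inhibitor of matrix metalloproteinases, at -0.27. Of 17 macrophage and leukocyte markers 16 had a negative difference (median -0.18, camera adjusted p = 0.00176, and adjusted p = 0.530 with an estimated correlation), with the complement gene C1qa at -0.39 and Cd52 at -0.32. All 7 measured adipocyte markers had a negative difference (median -0.59, mean -0.67, camera adjusted p = 0.0298, and adjusted p = 0.638 with an estimated correlation), with the lipid droplet protein Plin1 at -1.14 and leptin (Lep) at -0.54. Plin1 was detected on 2 of 3 arrays in each group, and Lep on 2 of 3 in KO. In all 3 lists 0 members passed over all genes by limma and 0 adjusted over the list alone. The array WT 3 stood apart from the rest: on the first principal component, with 44.1% of the variance, it lay at 32.3 and the other arrays between -14.6 and 8.31. The 8.31 was that of KO 3, the array with the same number, and the next highest was WT 1 at -5.31. WT 3 and KO 3 were also alike in cell cycle genes, whose median lay at -0.23 and -0.20 from the mean over all arrays. On the other arrays that median lay between 0.06 and 0.13. On WT 3 the median adipocyte marker lay 1.82 above its mean over all arrays, against -0.85 to -0.09 on the others, and the median macrophage marker lay 0.25 above. Without WT 3 the adipocyte mean turned to 0.03 (camera adjusted p = 0.917), and it lost its call without KO 1 (-0.57, adjusted p = 0.0937) and without KO 3 (-0.70, adjusted p = 0.0590), within a range of 1.82e-05 to 0.917 over its alternatives. Without WT 3 the macrophage mean was -0.09 (camera adjusted p = 0.209, within a range of 2.38e-05 to 0.530 over its alternatives), whereas the fibroblast list kept its call without each array in turn.

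**Figure D3:**
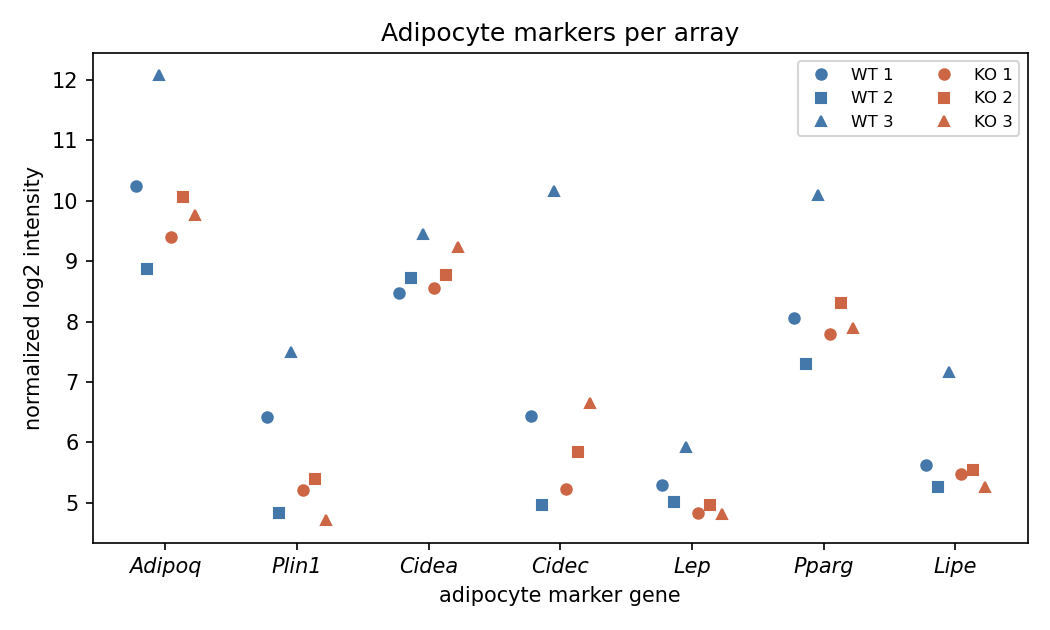
Log2 normalised intensity (vertical axis) of the 7 measured adipocyte markers (horizontal axis), with a point for each of the 3 WT and 3 KO arrays. WT 3 is the highest array for each gene, with the median marker 1.82 above its mean over all arrays.

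The remaining cell type lists did not pass. Endothelial markers had a median of -0.08 over 14 (camera adjusted p = 0.187), with Ramp2 at -0.16 and Esam at -0.12, and passed without WT 1 (mean -0.14, adjusted p = 0.0463), WT 2 (mean -0.15, adjusted p = 0.0284) or KO 3 (mean -0.15, adjusted p = 0.0392), within a range of 0.0284 to 0.823 over their alternatives. Without WT 3 their mean was 0.03. Erythroid markers had a median of -0.07 over 6 (camera adjusted p = 0.487), with the anion exchanger Slc4a1 at -0.43 and Sptb at 0.10. Schwann cell and nerve markers had a median of 0.02 over 6 (camera adjusted p = 0.817), with Egr2 at 0.15 and Ngfr at -0.09. Smooth muscle and pericyte markers had a median of -0.03 over 11 (camera adjusted p = 0.571). Their member Acta2, smooth muscle actin, had a difference of -0.48 (SE 0.09, limma adjusted p = 0.190) and was the 1 member past the threshold adjusted over the list alone. It passed over all genes without background correction and with the authors' values (adjusted p = 0.0398 by limma in both, within a range of 0.0398 to 0.638 over its alternatives). Cartilage and bone markers had a median of -0.02 and a mean of 0.03 over 7 (camera pointing up, adjusted p = 0.817), with Ibsp, detected on 2 of 3 arrays in each group, at 0.15 and Acan at -0.15. The keratinocyte list had 2 measured members, Lor at -0.22, detected on 2 of 3 arrays in each group, and Krt10 at -0.10, too few for the test. Across all 24 lists tested, camera called 5 higher and 3 lower, 0 with an estimated correlation, where the smallest adjusted p was 0.226, and fry called 2. The 5 higher lists are not independent, because the slow fibre list shares members with the Z-disc, thin filament and thick filament lists. Over all genes the median difference was -0.0022, and -0.03 with median centring.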

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

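The lists without their called members were tested after the result was seen, and all other alternatives were planned. Klhl40 kept its direction and call in all 13 alternatives (-6.11 to -3.87, limma adjusted p 3.31e-05 to 0.0412). Of the other named genes, outside the settings that left out an array, 373 values kept their direction and side of the threshold, 16 lost the call, 2 gained it and 1 reversed, Neb at -0.025 with median centring, at a level near background. Of the list values 199 kept both, 15 lost the call, 4 gained it and 1 reversed. Causes were not tested unless stated.

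The count of genes moved most. Limma called 23 higher and 8 lower without background correction (14 and 5 of them among the 15 and 5), 23 and 8 with the authors' values (14 and 5), and 23 higher with normexp without controls (15). Every probe tested as itself gave 23 higher. Trend and robust settings gave 34 and 10 and array weights 35 and 11, each with all 15 and 5. An adjusted p under 0.1 gave 30 and 10, and a log2 difference of at least 1 left 3 lower, by construction. Without a detection filter limma called 0 higher and 1 lower, with 1945 of 29453 genes at an unadjusted p under 0.05; the cause was not tested. Under the stricter filter Klhl40 and Ces5a were not tested. With the littermate pairs as a block 18 were higher and 8 lower, and apart from Xirp2, Fam78a and Fcer1a and the calls gained, the block changed no other call among the named genes and the lists. Leaving out each array in turn gave 0 to 15 higher and 1 to 10 lower, with fewer arrays in each fit.

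Glycolysis genes passed camera without background correction (mean -0.074, adjusted p = 0.0447), with the authors' values (-0.074, adjusted p = 0.0449) and without a filter (-0.078, adjusted p = 0.0160), within a range of 0.0146 to 0.660. Fasting genes passed without a filter (0.14, adjusted p = 0.0479, range 0.0325 to 0.630), and the camera direction of erythroid markers turned there (mean -0.011, adjusted p = 0.569, range 0.118 to 0.831). Adipocyte markers lost their call with median centring (-0.70, adjusted p = 0.0682, range 1.82e-05 to 0.917). With an estimated camera correlation the 8 called lists lost their call at the same means: thin filament 0.14, thick filament 0.26, Z-disc 0.55, slow fibre 0.76, chaperone 0.32, fibroblast -0.12, macrophage -0.17 and adipocyte -0.67. Fry, which sets no list against other genes, did not call thin filament (0.14, adjusted p = 0.179), thick filament (0.26, 0.179), slow fibre (0.76, 0.0683), fibroblast (-0.12, 0.150), macrophage (-0.17, 0.464) or adipocyte genes (-0.67, 0.724).

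Leaving out each array in turn, list means ranged from 0.10 to 0.17 for thin filament, 0.19 to 0.30 for thick filament, -0.24 to -0.089 for macrophage and -1.22 to 0.025 for adipocyte genes, each losing its call at least once. Z-disc, slow fibre, chaperone and fibroblast lists kept their calls throughout. Among lists not called, means ranged from -0.065 to 0.051 for fast fibre, -0.021 to 0.10 for neuromuscular junction, -0.042 to 0.087 for excitation-contraction coupling, 0.079 to 0.13 for atrophy, 0.058 to 0.22 for fasting, 0.0037 to 0.055 for oxidative phosphorylation, -0.13 to -0.051 for glycolysis and -0.13 to 0.048 for cell cycle genes. Those of other cells ranged from -0.15 to 0.032 for endothelial, -0.20 to 0.060 for erythroid, -0.076 to 0.13 for Schwann cell, -0.12 to 0.063 for smooth muscle and -0.093 to 0.21 for cartilage and bone markers. Named genes that changed sign, none of them called, ranged from -0.24 to 0.16 (Neb), -0.25 to 0.0077 (Krt10), -0.21 to 0.066 (Ngfr) and -0.31 to 0.10 (Acan). Signal over background limits Klhl40 (detected on 1 of 3 arrays in KO), Ces5a and Hspa1a (1 of 3 in WT), Lep (2 of 3 in KO), Plin1, Ibsp and Lor (2 of 3 in each group), and Neb, detected on all arrays at a low level.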

Other observations

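The splits of the arrays, the second adipocyte list and the intestinal list were planned before their results were seen, and all other tests here, and the condition on the spread of the intestinal list, were chosen after the result was seen. Between an adjusted p of 0.05 and 0.1 limma placed a further 20 genes, 15 higher and 5 lower in KO, whose groups do not overlap. They were named after their values were seen, and none passed the threshold. Abra, an actin-binding activator of serum response factor signalling, had a difference of 1.16 (SE 0.16, limma adjusted p = 0.0594), and Rcan1, a regulator of calcineurin, had 1.00 (SE 0.16, limma adjusted p = 0.0884). Hspa1l, an Hsp70 relative, had 1.37 (SE 0.20, limma adjusted p = 0.0730), and Mustn1, a small nuclear protein of muscle and skeleton, had 0.72 (SE 0.10, limma adjusted p = 0.0545). Lower were Ky, a muscle protein whose loss causes kyphoscoliosis in mice, at -1.12 (SE 0.16, limma adjusted p = 0.0762), and Ddit4l, an inhibitor of mTOR signalling, at -1.06 (SE 0.17, limma adjusted p = 0.0884). With the littermate block in limma, Abra and Ky had an adjusted p of 0.0287, and Rcan1, Hspa1l and Ddit4l had 0.0459.

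Z-disc and slow fibre genes were higher together in KO. A smaller share of cells other than muscle fibres in KO could raise fibre genes, and the fibroblast list did have a median of -0.13. However, 27 fast fibre and excitation-contraction coupling genes outside both lists had a median of 0.0060 (SD 0.36), below the Z-disc median of 0.44. Of the 27, 1 lay above that median, which argues against this as the whole cause. Some of the 27, such as Tnnc2 and Mylpf, were among the brightest probes, where the normalisation can hold a difference near 0. On the scanner's scale their means were 30496 and 33391 in WT, and 30103 and 32532 in KO. WT 3 as the sole source is argued against by the Z-disc mean of 0.47 without it. A response of the fibres to the loss of Klhl40 may remain, as a hypothesis the data do not test, since all KO animals share the genotype.

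The 6 arrays can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split called 20 genes by limma, and the highest of the others called 0, so 1 of 10 splits reached that count. Of the 4 splits that part all littermate pairs, 1, the real one, reached it. At an unadjusted limma p under 0.05 the real split gave 978 genes and was not the highest. The split of WT 1, WT 2 and KO 1 against the rest gave 1386, and that of WT 1, WT 3 and KO 3 gave 1296. Neither of these parts the genotypes. For lists the real split called 8 by camera and the highest of the others 13, and 4 of 10 splits called at least 8. Among the 4 splits that part all pairs 2 called at least 8.

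Hhatl, next to Klhl40 on the chromosome, was lower in KO by a difference of -0.98. The 19 other tested genes nearest to Klhl40 had a median of -0.042 (SD 0.17), with no absolute difference above 0.34. None of the 19 was called by limma. At an unadjusted limma p under 0.05 were 2, Sec22c at -0.31 and Ano10 at -0.34, where 7.3% of all genes were. Besides Hhatl, the closest tested genes lay at positions -3 and 6 from Klhl40 in the annotated order, and the set reached from -50 to 31. The values argue against an effect of the altered locus across that stretch. They do not cover the untested genes nearest to it. An effect of the altered allele on Hhatl, alone or with untested genes near it, or on the match of its probe, could also give the difference. These cannot be told apart from a response to the loss of Klhl40, because Hhatl had 1 detected probe and all KO animals carry the allele.

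Genes of other tissues stood out on WT arrays, and on WT 3 the second adipocyte list lay 0.97 (median) above the mean of the other arrays, against -0.26 to -0.06 for the other arrays. Of its 16 measured genes 12 were highest on WT 3, such as Mgll at 9.62 against 8.12 to 8.60, and the abundant Adipoq of the first list lay at 12.08 against 8.87 to 10.25. This is consistent with more adipose tissue in that dissection, although 12 of the 16 were detected on all 6 arrays, where muscle and adipocytes present in every dissection were not separated, and a poor array is argued against by its 19074 detected probes, within the range of the others. On WT 2, Prap1 (9.95), Apoa4 (9.08) and Guca2a (8.23), known from the intestine, were highest, with 6.89, 6.98 and 5.47 on WT 3, 6.37, 6.18 and 5.34 on KO 2, 5.43, 5.37 and 4.69 on KO 3, and 4.32 to 4.53 on WT 1 and KO 1. Of 31 genes of the intestinal list on the array, the 10 measured had a median of -0.038 on WT 2. By the bound planned beforehand this counts against intestinal tissue or its RNA. It stays open only through the condition on the spread (SD 0.51), added after the result was seen. Highest on WT 2 were 2 of the 10, Cdx2 (5.36 against at most 4.63) and Clca1 (5.91 against at most 5.34), whereas 3 were highest on WT 1. The intestinal genes Fabp1 (4.29), Fabp2 (4.27), Apoa1, Epcam, Reg3g, Sis and Vil1 were not detected on WT 2. For Prap1, Apoa4 and Guca2a no explanation other than intestinal tissue or its RNA was tested.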
